A study of Mus musculus with 9 samples.

How the data were processed

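RNA from mouse vascular tissue was sequenced in 9 libraries. Per the labels' protocols, tissue was frozen on dry ice, RNA was extracted with Trizol and libraries were made by standard Illumina protocols. Per the series design text, reads were paired and came from a NovaSeq instrument, and groups were compared by the authors with DESeq2 1.20.0. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to mm10. The read counter, the annotation release and the formula of the values are not given in the sources used here.

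The deposited values are FPKM, normalized for exon length and depth by the authors, with 1 column per library and no pooling of replicates. The table held 54532 genes by Ensembl identifier, of which 54409 had a symbol. Gene positions and exon lengths came from an annotation of GRCm38, the assembly that mm10 names, which matched 54495 of the genes. The value of 1 fragment in each library was found from 2000 low genes and their exon lengths. With it, 97.1 to 97.3% of the values in each library were whole fragments within 0.1, which gave totals of 15837599 to 17381974 fragments per library. The divisor implied by the FPKM values followed median-of-ratios size factors of these fragments, with a largest difference of 1.16% over the 9 libraries, and not the library totals. FPKM are not counts, so no count test was the main test, although the series design text names one.

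Each library was assigned to its group by its genotype and treatment labels. The main test was limma 3.58.1 (eBayes with a trend, not robust) in R 4.3.3 on log2(FPKM + 0.5), two-sided, with the 3 group means of all 9 libraries in 1 fit, which leaves 6 residual degrees of freedom. Genes entered with a mean of at least 0.5 FPKM over all libraries, which kept 15610. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 3 comparisons came from the same fit, SAHH-het minus SAHH-WT, SAHH-het+betaine minus SAHH-het and SAHH-het+betaine minus SAHH-WT. Genes moved back by betaine were those called in the first and called in the second with the opposite sign, and 100 draws of unchanged groups that share the middle group gave the values by chance, and 100 further draws with same-numbered SAHH-WT and SAHH-het libraries correlated were added after seeing the results. Ahcy was also compared by exact permutation tests on its log2 values.

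The design, the filter, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. There were 42 lists with 565 members, all found in the table, of which 522 were tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes, while fry asks whether a list's genes move on balance in 1 direction. Lists of adrenal cortex, adrenal medulla, hepatocyte and thymocyte genes were added after seeing the data and before they were tested.

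The rule for named genes was as follows. Ahcy and Apoe were named in every library. For the first 2 comparisons, the 10 called genes with the largest change in each direction were named, among genes with a symbol, a mean of at least 1 FPKM and no overlap between the groups, leaving out predicted genes and pseudogenes. Where fewer than 5 passed in a direction, the 5 with the smallest p were named as values that did not pass. The third comparison took 5 per direction, and genes moved back up to 5 per direction. From each list described, up to 4 members were named, those with the smallest p and those with the highest mean. In the third comparison only the 2 members with the smallest p were named. Other genes named from the lists are those counted as passing adjusted over the list alone, and the markers of tissue content were chosen after their values were seen.

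The alternatives were pseudocounts of 0.1 and 1, a filter at a mean of 1 FPKM and none, TPM rescaling, scaling by the median ratio, quantile normalization, the replicate number as a block, robust eBayes, sample weights, leaving out each library in turn, only the libraries of the 2 groups compared, and other thresholds. limma with voom on the recovered fragments was added after seeing the data. It called 4, 2 and 0 genes in the 3 comparisons. The replicate numbers were checked by correlating the deviations of same-numbered libraries from their group means. The 3 pairs of SAHH-WT with SAHH-het libraries correlated at 0.29, 0.23 and 0.18, all over 0.1, and the other 6 of 9 pairs at -0.35 to 0.08, with 4 of 9 libraries correlating best with their own number. The labels do not say what a number marks, so any pairing comes from the data alone and does not extend to SAHH-het+betaine. A block by number in SAHH-WT and SAHH-het only was therefore added after seeing the results. A correction for exon length, with and without this block, was added then too. It takes off each library's deviation from the gene means as smoothed on log2 exon length, and it called 4, 2 and 0 genes in the 3 comparisons. No 2 libraries held identical values, and none was left out of the main test.

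The scripts were tested on simulated data. For SAHH-het minus SAHH-WT, 200 genes among 15600 were changed in each of 10 runs, and the test recovered 10% of those changed 2-fold, 63.8% at 4-fold, 84.4% at 16-fold and 86.0% at 64-fold, with 6.29% of its calls false. The spread was drawn independently for each gene, while genes in these libraries are correlated. More genes were also changed than were called here, so these rates may not carry over. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used to read the table and draw the figures.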

Results

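RNA from vascular tissue of C57BL/6 mice aged 24 weeks was sequenced in 9 libraries, 3 in each of 3 groups. By the labels all mice carried the ApoE-null background, on which mice are prone to atherosclerosis. The SAHH-WT group had wild-type SAHH, the SAHH-het group was heterozygous for SAHH, and the SAHH-het+betaine group was heterozygous and received betaine. SAHH is S-adenosylhomocysteine hydrolase, encoded by Ahcy, the enzyme that splits S-adenosylhomocysteine, the by-product of methyl transfer, into homocysteine and adenosine. Betaine is a methyl donor used to turn homocysteine back into methionine. The dose and length of the betaine treatment are not given in the sources used here. The labels do not say that the libraries of a group came from separate animals, so the p-values below measure only the spread between these libraries. Part of that spread may be technical, such as the tissue taken, but genes of other tissues differ within groups in a way that repeat libraries of 1 RNA sample would not.

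The values were FPKM for 54532 genes. The number of fragments behind them, recovered from the steps of the FPKM values, lay between 15837599 and 17381974 per library. Between 21829 and 24467 genes were above 0 in a library. Mitochondrial genes made up 21.8 to 39.4% of the FPKM sum and 9.18 to 19.5% of the recovered fragments. The tests used the 15610 genes with a mean of at least 0.5 FPKM. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes, and adjusted p-values are Benjamini-Hochberg values from limma. Means are given as mean ± SD over the 3 libraries of a group.

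Ahcy (ENSMUSG00000027597, protein-coding, chromosome 2, 155059310 to 155074497, GRCm38), the targeted gene, checks the SAHH labels. It measured 11.5, 7.17 and 7.98 FPKM in SAHH-WT libraries 1 to 3 (8.90 ± 2.32). It measured 3.48, 3.89 and 4.75 FPKM in the libraries labelled SAHH-het (4.04 ± 0.649), which is 0.454 of the SAHH-WT mean. It measured 7.66, 9.70 and 8.63 FPKM in the libraries labelled SAHH-het+betaine (8.66 ± 1.02), which is 0.973 of the SAHH-WT mean. The log2 change was -1.03 for SAHH-het minus SAHH-WT (95% interval -1.51 to -0.55, limma adjusted p = 0.274) and 1.02 for SAHH-het+betaine minus SAHH-het (0.54 to 1.49, limma adjusted p = 0.460). It was -0.02 for SAHH-het+betaine minus SAHH-WT (-0.49 to 0.46, limma adjusted p = 0.985). The SAHH-het libraries overlapped neither of the other groups. Two-sided exact permutation tests of Ahcy gave p = 0.1, 0.1 and 0.9 for these 3 differences, and 0.1 is the smallest p that 3 libraries against 3 allow. The libraries labelled SAHH-het+betaine thus lack the lower Ahcy mRNA level of the libraries labelled SAHH-het, although both carry the heterozygous label. Genotype and betaine cannot be told apart as the source of this level, since all 3 libraries share both. Tissue content as its source was tested only for liver. Which part of the gene the allele lacks is not given in the sources used here.

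Apoe (ENSMUSG00000002985, protein-coding, chromosome 7, 19696109 to 19699188), the apolipoprotein that clears lipoprotein remnants, checks the ApoE-null label. It measured 2.91, 4.35 and 6.11 FPKM in the libraries labelled SAHH-WT and 5.51, 8.88 and 7.32 FPKM in those labelled SAHH-het+betaine. In the libraries labelled SAHH-het it measured 149, 223 and 225 FPKM. The lowest SAHH-het value was 16.8 times the highest value of the other 6 libraries. The Apoe level of the SAHH-het libraries therefore goes against the ApoE-null label that all 3 groups share, and every direction given below for SAHH-het rests on libraries whose Apoe level differs from that of the other groups. How the null allele was made is not given in the sources used here, so the level of Apoe RNA alone does not give a genotype.

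**Figure D1:**
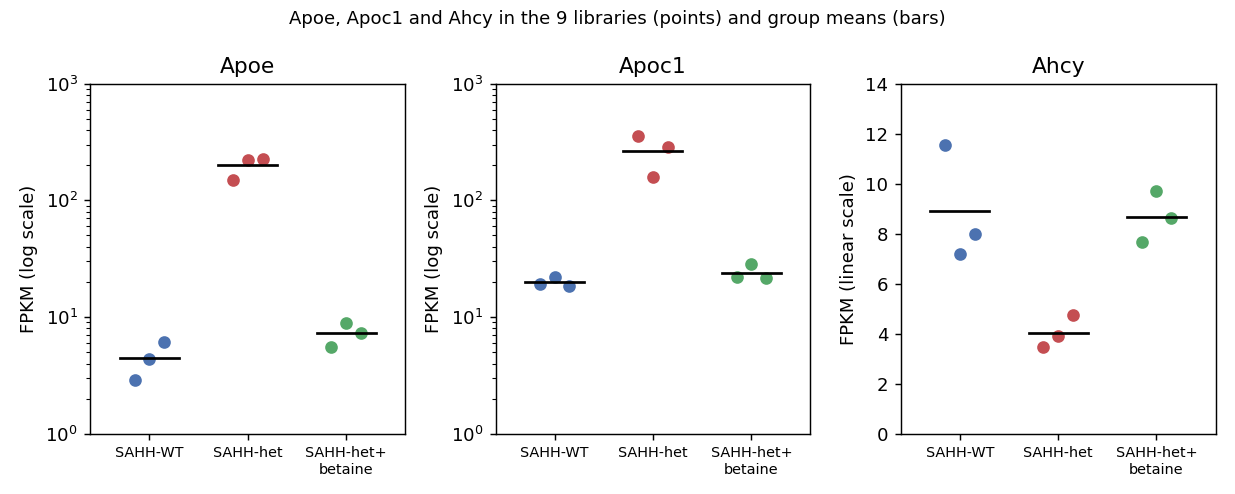
FPKM of Apoe and Apoc1 (log scale) and of Ahcy (linear scale) in each of the 9 libraries, with points for libraries and bars for group means. Apoe is at 149 to 225 FPKM in the SAHH-het libraries and at 2.91 to 8.88 FPKM in the others, and Ahcy is at 3.48 to 4.75 FPKM in the SAHH-het libraries and at 7.17 to 11.5 FPKM in the others.

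The libraries differed in tissue content within groups. Smooth muscle genes were present in every library, with Myh11, the smooth muscle myosin heavy chain, between 4.76 and 24.2 FPKM. Acta2, smooth muscle actin, lay between 37.8 and 163 FPKM. Fat cell genes were present in every library too, with Adipoq between 157 and 697 FPKM and Plin1 between 46.3 and 302 FPKM. No value here gives the share of fat or vessel wall, so the lists below cannot be assigned to the vessel wall alone. Ucp1, the uncoupling protein of brown fat, ranged from 18.0 FPKM in SAHH-WT 1 to 5768 FPKM in SAHH-het+betaine 3. Acta1, skeletal muscle actin, ranged from 0.164 FPKM in SAHH-WT 3 to 4564 FPKM in SAHH-het 1, and Myh6, a cardiac myosin, from 0.0333 FPKM in SAHH-het 2 to 158 FPKM in SAHH-het+betaine 2. Cd79a, a part of the B cell receptor, measured 1.88, 110 and 43.9 FPKM in SAHH-WT 1 to 3, 8.44, 7.03 and 4.55 FPKM in SAHH-het, and 61.4, 15.4 and 8.02 FPKM in SAHH-het+betaine. SAHH-WT 1 stood apart through genes of steroid synthesis in the adrenal cortex. Hsd3b1 was at 4239 FPKM and Cyp21a1 at 2900 FPKM there, while Cyp21a1 was listed at 0 in the other 8 libraries and Hsd3b1 did not exceed 0.0319 FPKM in them. The gene lists for cell types and pathways are described below with these levels beside them.

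**Figure D2:**
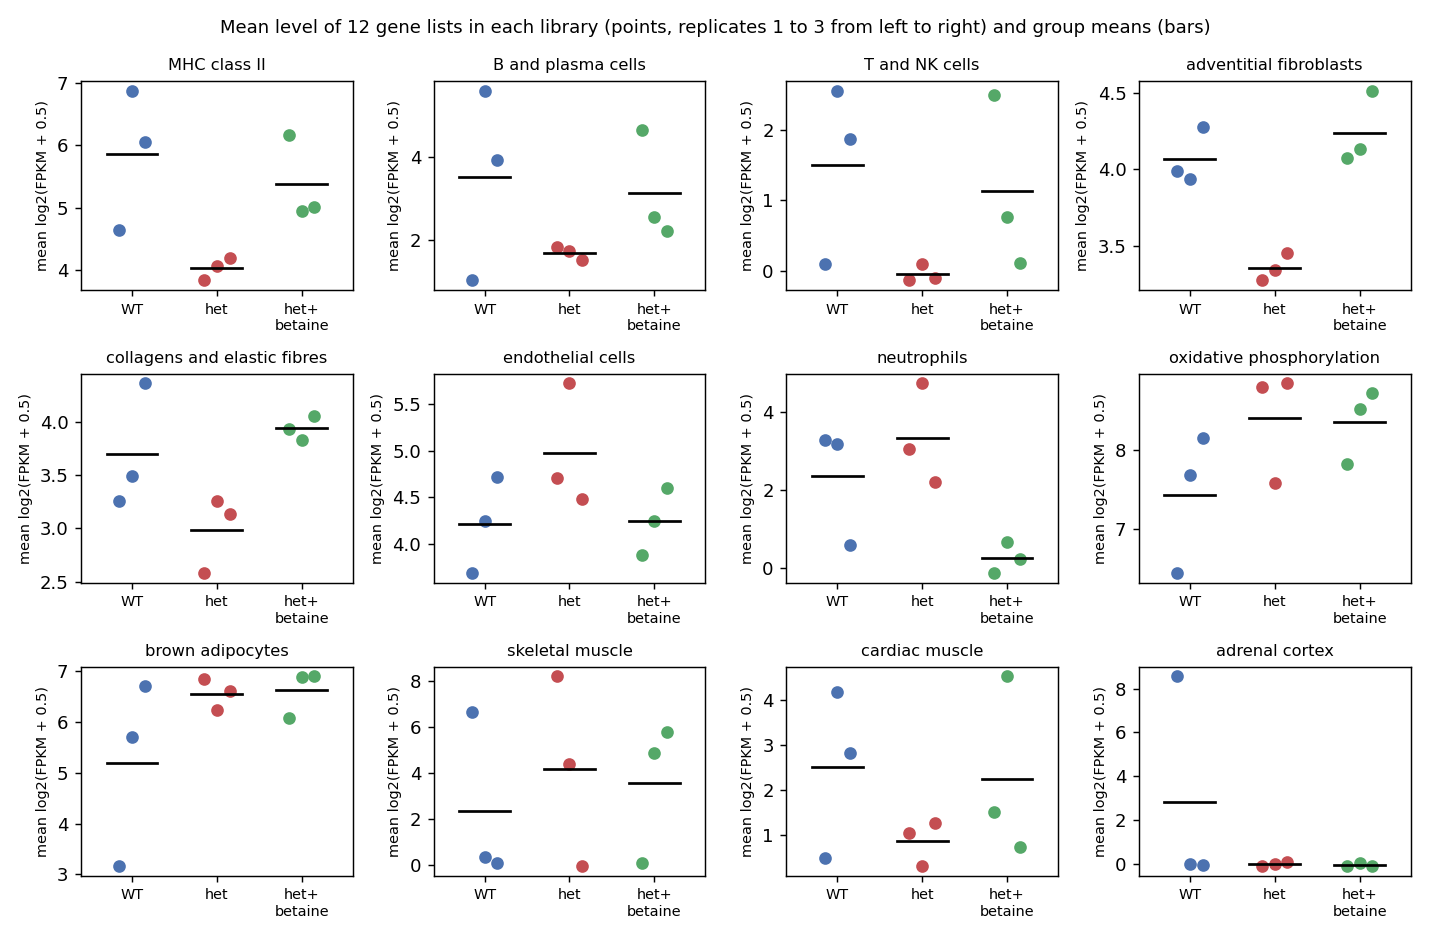
Mean log2(FPKM + 0.5) over all members of 12 gene lists, tested or not, in each library (points, libraries 1 to 3 of a group from left to right) with group means (bars). The adrenal cortex list is high in SAHH-WT 1 and near 0 in the others, and the lists of lymphocytes and MHC class II spread within SAHH-WT and SAHH-het+betaine. The skeletal muscle list spreads within all 3 groups, and the cardiac muscle list within SAHH-WT and SAHH-het+betaine but little within SAHH-het.

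The comparison of SAHH-het with SAHH-WT asks what the heterozygous SAHH allele does on the ApoE-null background. In the libraries labelled SAHH-het, Apoe and its neighbour Apoc1 were far higher than in SAHH-WT, and Map3k6 and Gstt2 were higher by smaller factors. By camera with its preset correlation, lists of antigen presentation, lymphocytes, adventitial fibroblasts and collagens were lower, and lists of oxidative phosphorylation, endothelium and brown and white fat were higher. Each of these list calls was lost with an estimated correlation (adjusted p = 0.743 with an estimated correlation), and when single libraries were left out the calls for both fat lists and for B and plasma cells were also lost. limma called 4 of 15610 genes, all 4 higher in SAHH-het. At an unadjusted p under 0.05 there were 1945 genes, 1140 higher and 805 lower, against 780.5 expected by chance. In 16.6% of tested genes the 2 groups of libraries did not overlap, against 10% by chance. Both values by chance are averages. Genes are not independent replicates, so such numbers can vary widely by chance, here and in the other 2 comparisons.

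Apoe rose from 4.46 ± 1.60 to 199 ± 43.4 FPKM, a log2 change of 5.36 (SE 0.29, adjusted p = 0.000662). Apoc1 (ENSMUSG00000040564, chromosome 7, 19689481 to 19692660), which encodes an apolipoprotein of lipoprotein particles and lies 3.45 kb from Apoe, rose from 20.0 ± 1.94 to 266 ± 99.7 FPKM (log2 change 3.63, SE 0.29, adjusted p = 0.00807). Map3k6 (ENSMUSG00000028862, chromosome 4, 133240818 to 133252929), a kinase of the stress-activated MAP kinase cascade, rose from 4.25 ± 0.252 to 14.5 ± 2.53 FPKM (log2 change 1.65, SE 0.16, adjusted p = 0.0240). Gstt2 (ENSMUSG00000033318, chromosome 10, 75831114 to 75837424), a glutathione S-transferase, rose from 6.38 ± 0.964 to 19.9 ± 1.67 FPKM (log2 change 1.57, SE 0.16, adjusted p = 0.0240). All 4 were higher in 3 of 3 SAHH-het libraries than in any SAHH-WT library. Apoe was called in 21 of 21 alternative settings, Apoc1 in 17, Map3k6 in 11 and Gstt2 in 10. When single libraries were left out, Gstt2 was never called and Map3k6 was called only without SAHH-het 2. With the replicate number as a block in the SAHH-WT and SAHH-het libraries, Gstt2 was not called (adjusted p = 0.124), and Apoe, Apoc1 and Map3k6 were. The mitochondrial tRNA gene mt-Tg did not pass without this block (adjusted p = 0.0599) and passed with it (adjusted p = 0.0189). It measured 43.6, 24.7 and 25.6 FPKM in SAHH-het and 2.16 FPKM in SAHH-WT 1, and was listed at 0 in SAHH-WT 2 and 3.

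No gene passed as lower. The 5 genes with the smallest p in that direction are given as values that did not pass. Cyp1b1, a cytochrome P450, had a log2 change of -2.05, from 13.5 to 2.90 FPKM. The complement regulator Cd55 had -1.87, the secreted chaperone Clu -2.44 and Ogn, a small proteoglycan of the matrix, -1.53. The adjusted p of each of these 4 was 0.166. The small nucleolar RNA Snord42b was listed at 0 in 2 SAHH-het libraries and measured 0.811 FPKM in SAHH-het 2, against 3.55 to 10.1 FPKM in SAHH-WT (adjusted p = 0.237). It is a very short gene, so its FPKM values rest on few fragments.

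Of the 42 gene lists, camera with its preset correlation called 13, 4 higher and 9 lower in SAHH-het. No list passed with an estimated correlation, where each of these 13 had an adjusted p = 0.743 with an estimated correlation, and none passed with fry, whose lowest adjusted p was 0.142. The estimated correlation between members of these 13 lists ran from 0.0808 (RNA m6A machinery) to 0.977 (MHC class II), above the preset 0.01. It was 0.932 for B and plasma cells and 0.935 for oxidative phosphorylation. Members of such a list are close to repeats of 1 difference, and the camera p-values with the preset correlation are too small for them. Over the lists 0 members passed over all genes tested, and 23 passed adjusted over the list alone.

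Genes of antigen presentation and lymphocytes were lower as lists. All 7 MHC class II genes were lower (median log2 change -1.86, camera adjusted p = 1.03e-05), and all 7 passed adjusted over the list alone. H2-Aa went from 202 to 38.3 FPKM, H2-Eb1 from 262 to 61.0 FPKM and Cd74, the invariant chain, from 634 to 116 FPKM. All 13 tested T and NK cell genes were lower (median -1.69, camera adjusted p = 4.72e-05), with 0 of them passing adjusted over the list alone. The T cell receptor gene Cd3g had a log2 change of -2.04, the interleukin receptor gene Il7r -2.05, Cd2 -1.08 and the granule protein gene Nkg7 -1.67. All 12 B and plasma cell genes were lower (median -1.66, camera adjusted p = 0.000609), again with 0 passing adjusted over the list alone. The immunoglobulin gene Ighm was at 660 FPKM in SAHH-WT and 96.2 FPKM in SAHH-het, and Jchain at 89.1 and 17.3 FPKM. Of the genes for other surface receptors of B cells, Cr2 was at 4.36 and 0.0553 FPKM and Fcer2a at 8.48 and 0.0770 FPKM. These lists moved with the lymphocyte content of single libraries: SAHH-WT 1 had Cr2 at 0.0967 FPKM, within reach of the SAHH-het libraries, and SAHH-WT 2 had 8.30 FPKM. Without SAHH-WT 2 the B and plasma cell list had a median of -0.64 and its call was lost (adjusted p = 0.0776), and without SAHH-WT 1 its median was -3.31. The median of the T and NK cell list was -1.19 without SAHH-WT 2 and -2.55 without SAHH-WT 1, and it stayed called.

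Genes of the adventitia and the extracellular matrix were lower as lists too. All 11 tested adventitial fibroblast genes were lower (median -0.72, camera adjusted p = 1.14e-05), and 4 passed adjusted over the list alone, Pdgfra, Lum, Serpinf1 and Dpt. Lum, a proteoglycan of collagen fibrils, had a log2 change of -1.53 and Dpt, a matrix protein, -1.02. Decorin (Dcn) had -0.72 and the actin-severing protein Gsn -0.37. Of 15 genes for collagens and elastic fibres, 12 were lower (median -0.75, camera adjusted p = 0.000164), and 5 passed adjusted over the list alone, Col1a1, Col1a2, Col3a1, Col5a1 and Col6a1. Col1a2, a chain of fibrillar collagen I, fell from 15.7 to 4.34 FPKM by that adjustment, and Col5a1 from 5.65 to 2.19 FPKM. The basement membrane collagens Col4a1 and Col4a2 had log2 changes of 0.06 and 0.33, and that of Col4a1 was -0.24 with TPM rescaling and -0.16 with quantile normalization. Among matrix proteases and inhibitors 13 of 16 were lower (median -0.53, camera adjusted p = 0.0135). The membrane-bound protease gene Mmp14 (-0.93) and the inhibitor gene Timp2 (-0.80) passed adjusted over the list alone, and the lysosomal protease gene Ctss had -1.48. Without SAHH-WT 3 the median of the collagen list was -0.32, and the protease list had a median of -0.21 and was no longer called (adjusted p = 0.335), nor was it without SAHH-het 1 (adjusted p = 0.123).

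Lists of proliferation, senescence and RNA methylation were also lower. All 16 tested cell cycle genes were lower (median -0.53, camera adjusted p = 0.000728), with 0 passing adjusted over the list alone. The mitotic genes Ccnb2 and Cdc20 had log2 changes of -1.14 and -1.05, and the replication genes Mcm6 and Pcna -0.59 and -0.16. In the senescence list 11 of 12 were lower (median -0.47, camera adjusted p = 0.000728), with 0 passing adjusted over the list alone. The cell cycle inhibitor Cdkn2a had -1.19, the stress cytokine Gdf15 -1.04, and the binding proteins of insulin-like growth factors Igfbp5 and Igfbp7 -0.99 and -0.44. All 13 genes of the RNA m6A machinery were lower by small amounts (median -0.18, camera adjusted p = 0.0147), with 0 passing adjusted over the list alone. These are long genes, with a median exon length of 6283 against 4343 over all genes, and longer genes were lower in this comparison. After a correction for exon length the list had a median of -0.14 and an adjusted p = 0.0497, and with the replicate block as well its call was lost (adjusted p = 0.0612). The writer component Rbm15 had -0.36, the eraser Alkbh5 -0.03 (0.00273 after that correction), and the readers Ythdf3 and Igf2bp2 -0.15 and -0.59. The cell cycle list had a median of -0.30 without SAHH-WT 2 and -0.96 without SAHH-het 2, and the senescence list -0.31 without SAHH-WT 1.

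Genes of mitochondria, fat and endothelium were higher as lists. All 20 oxidative phosphorylation genes were higher (median 0.91, camera adjusted p = 1.14e-05), with 0 passing adjusted over the list alone. Cox5b had a log2 change of 1.70, Ndufa1 1.55, Atp5b 0.90 and Atp5a1 0.73. In the brown adipocyte list 11 of 12 were higher (median 1.84, camera adjusted p = 0.00130), and Cpt1b, which carries fatty acids into mitochondria, passed adjusted over the list alone, at 0.507 FPKM in SAHH-WT and 2.94 FPKM in SAHH-het. Cox8b had 1.94, Cox7a1 1.92 and Ucp1 2.12, and Ucp1 turned to -0.25 without SAHH-WT 1. In the white adipocyte list 11 of 14 were higher (median 0.87, camera adjusted p = 0.00936), with 0 passing adjusted over the list alone. Fabp4 had 1.19, the hormone-sensitive lipase gene Lipe 1.15, the lipid droplet gene Plin4 1.02 and adipsin (Cfd) -0.02. In the endothelial list 15 of 16 were higher (median 0.83, camera adjusted p = 4.72e-05), with 0 passing adjusted over the list alone. Egfl7 had 1.18, the transcription factor Sox17 0.97, the cadherin Cdh5 0.83 and the co-receptor Eng 0.83. SAHH-WT 1, the library with adrenal genes, held the lowest Ucp1 of all 9 libraries. Without it the medians were 0.40 for oxidative phosphorylation, 0.53 for endothelium, 0.30 for brown adipocytes and 0.27 for white adipocytes, and both adipocyte calls were lost (adjusted p = 0.187 and 0.211). The white adipocyte call was also lost without SAHH-het 3 (adjusted p = 0.0815), its median was 1.32 without SAHH-WT 3, and that of the endothelial list was 0.42 without SAHH-het 2.

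The list closest to SAHH itself, the methionine cycle and transsulfuration, did not pass, with 9 of 12 genes lower (median -0.26, camera adjusted p = 0.0616, adjusted p = 0.743 with an estimated correlation). Ahcy and Mtap, which salvages methylthioadenosine, passed adjusted over the list alone as lower, with log2 changes of -1.03 and -0.61. The Ahcy-like gene Ahcyl1 had 0.44, and -0.0212 without SAHH-WT 1, and Mat2a, which makes S-adenosylmethionine, had -0.11. The DNA and histone methylation enzymes (15 of 21 lower, camera adjusted p = 0.103) and betaine, choline and folate metabolism (12 of 16 lower, camera adjusted p = 0.568) did not pass. Neither contractile smooth muscle (6 of 12 higher, camera adjusted p = 0.902) nor macrophages (11 of 16 lower, camera adjusted p = 0.242) passed.

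The comparison of SAHH-het+betaine with SAHH-het asks what betaine does in heterozygous mice, and by the levels of Ahcy and Apoe the libraries also differ in both targeted genes. In the SAHH-het+betaine libraries Apoe, Apoc1 and mt-Tg were lower than in SAHH-het. By camera with its preset correlation, lists of adventitial fibroblasts, collagens, MHC class II, lymphocytes and lipid synthesis were higher, and lists of neutrophils and endothelium were lower. All of these list calls were lost with an estimated correlation (adjusted p from 0.290 to 0.842 with an estimated correlation), and those for lymphocytes and lipid synthesis were also lost when single libraries were left out. limma called 3 of 15610 genes, all 3 lower. At an unadjusted p under 0.05 there were 1254 genes, 567 higher and 687 lower, against 780.5 expected by chance. In 16.4% of tested genes the groups did not overlap, against 10% by chance.

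Apoe fell to 7.23 ± 1.69 FPKM, a log2 change of -4.69 (SE 0.29, adjusted p = 0.00199), and Apoc1 fell to 24.1 ± 3.92 FPKM, a log2 change of -3.37 (SE 0.29, adjusted p = 0.0146). The tRNA gene mt-Tg (ENSMUSG00000064359, mitochondrial chromosome, 9391 to 9458) was listed at 0 in all 3 SAHH-het+betaine libraries (adjusted p = 0.0323). Each of the 3 was lower in 3 of 3 SAHH-het+betaine libraries than in any SAHH-het library. Apoe was called in 21 of 21 alternative settings, Apoc1 in 14 and mt-Tg in 9, not with the correction for exon length. Gstt2 (log2 change -1.36, adjusted p = 0.0630) and Map3k6 (-1.24, adjusted p = 0.109) did not pass.

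No gene passed as higher. The 5 with the smallest p in that direction are given as values that did not pass. Hr, a nuclear co-repressor, had a log2 change of 1.34 (adjusted p = 0.272) and Dpt 1.55 (adjusted p = 0.350). The collagen genes Col6a3 and Col1a2 had 1.03 (adjusted p = 0.356) and 1.77 (adjusted p = 0.366), and Ogn had 1.32 (adjusted p = 0.368).

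Of the 42 lists, camera with its preset correlation called 10, 8 higher and 2 lower in SAHH-het+betaine. None passed with an estimated correlation or with fry, whose lowest adjusted p was 0.0508. Over the lists 36 members passed adjusted over the list alone, and 0 list members passed over all genes tested.

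The adventitial fibroblast list had the smallest camera p. Of 11 genes, 10 were higher (median 0.93, camera adjusted p = 5.58e-10, adjusted p = 0.290 with an estimated correlation), and 8 passed adjusted over the list alone. Dpt went from 15.9 to 48.8 FPKM, the anti-angiogenic factor Serpinf1 from 8.84 to 19.4 FPKM and Gsn from 232 to 378 FPKM, while Dcn, which did not pass, had a log2 change of 0.50. In the list of collagens and elastic fibres 14 of 15 were higher (median 1.05, camera adjusted p = 1.65e-08, adjusted p = 0.647 with an estimated correlation), and 8 passed adjusted over the list alone. Col1a2 went from 4.34 to 15.8 FPKM and Postn, a matrix protein of remodelling tissue, from 8.05 to 17.5 FPKM. Col4a1 had 0.19 and Col4a2 -0.04, the latter above 0 with quantile normalization.

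Neutrophil genes were lower. All 11 were lower (median -3.02, camera adjusted p = 6.87e-10, adjusted p = 0.647 with an estimated correlation), and 9 passed adjusted over the list alone. The calprotectin genes S100a8 and S100a9 went from 259 to 4.78 FPKM and from 315 to 5.89 FPKM, the receptor for granulocyte colony-stimulating factor Csf3r from 9.16 to 1.25 FPKM and Retnlg from 72.4 to 1.31 FPKM. S100a8 varied within groups, at 104, 77.9 and 4.45 FPKM in SAHH-WT and 204, 525 and 48.4 FPKM in SAHH-het. The endothelial list was lower with 15 of 16 genes (median -0.73, camera adjusted p = 4.60e-06, adjusted p = 0.842 with an estimated correlation), and 0 passed adjusted over the list alone. Sox17 had a log2 change of -1.15, the adhesion molecule Esam -1.14, Eng -1.07 and Cdh5 -0.72. Without SAHH-het 2, the library with the highest endothelial level, its median was -0.35, and without SAHH-het+betaine 1 it was -0.49.

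Genes of antigen presentation and lymphocytes were higher as lists. All 7 MHC class II genes were higher (median 1.48, camera adjusted p = 2.39e-05), and H2-Aa, H2-Ab1, H2-Eb1 and Cd74 passed adjusted over the list alone. H2-Aa went from 38.3 to 117 FPKM, H2-Ab1 from 37.3 to 116 FPKM, H2-Eb1 from 61.0 to 179 FPKM and Cd74 from 116 to 363 FPKM. In the T and NK cell list 12 of 13 were higher (median 1.42, camera adjusted p = 0.000750), and in the B and plasma cell list 12 of 12 (median 1.53, camera adjusted p = 0.00246), with 0 members of either passing adjusted over the list alone. The adjusted p was 0.842 with an estimated correlation for each of these 3 lists. Cd3g had a log2 change of 1.64, the co-receptor Cd4 1.96, Cd2 0.78 and Nkg7 1.15. Fcer2a had 2.83, Cr2 1.82, Ighm 1.07 and Jchain 0.72, and Jchain turned to -0.11 without SAHH-het+betaine 1. These lists followed SAHH-het+betaine 1, the library of its group with the highest Cd79a. Without it the T and NK cell median was 0.62 (adjusted p = 0.169) and the B and plasma cell median 0.73 (adjusted p = 0.218), so both calls were lost.

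Lipid genes were higher as lists. In fatty acid synthesis 10 of 11 were higher (median 1.35, camera adjusted p = 0.00474), in cholesterol synthesis 10 of 13 (median 0.53, camera adjusted p = 0.0269) and among genes of lipid-loaded macrophages 15 of 15 (median 0.47, camera adjusted p = 0.00780). The adjusted p was 0.842 with an estimated correlation for each, and 0 members of the 3 lists passed adjusted over the list alone. The desaturase genes Scd1 and Scd2 had log2 changes of 2.10 and 1.70, the citrate lyase gene Acly 1.88 and the fatty acid synthase gene Fasn 1.53. Idi1 had 1.63, the sterol sensor partner Insig1 1.15 and Hmgcs1 0.54. Gpnmb, a marker of lipid-laden macrophages, had 2.05, the cholesterol exporter Abca1 0.68 and the lysosomal proteases Ctsb and Ctsd 0.28 and 0.18. Without SAHH-het 2, whose Scd1 was the lowest of all libraries at 435 FPKM, fatty acid synthesis had a median of 0.25 (adjusted p = 0.227) and cholesterol synthesis 0.07 (adjusted p = 0.854). The cholesterol synthesis call was also lost without SAHH-het+betaine 1 (adjusted p = 0.176) or SAHH-het+betaine 3 (adjusted p = 0.152). The call for lipid-loaded macrophages was lost without SAHH-het 3 (median 0.40, adjusted p = 0.119).

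The methionine cycle list did not pass (8 of 12 higher, camera adjusted p = 0.192, adjusted p = 0.842 with an estimated correlation). Ahcy passed adjusted over the list alone as higher. Gnmt, which uses S-adenosylmethionine to methylate glycine, had a log2 change of -1.26, Mat2a -0.15 and Ahcyl1 0.48. The list of betaine, choline and folate metabolism, the pathway of the treatment, did not pass (8 of 16 higher, camera adjusted p = 0.359).

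Genes moved back by betaine are those called in SAHH-het minus SAHH-WT and, with the opposite sign, in SAHH-het+betaine minus SAHH-het. There were 2, Apoe and Apoc1, where independent lists would share 0.000769 genes and simulated unchanged groups gave a median of 0. Neither value tests an effect of betaine. A gene that differs in the SAHH-het libraries alone enters both comparisons with opposite signs, and neither value allows for such a gene. The count was 1, without Apoc1, when SAHH-WT 2, SAHH-WT 3, SAHH-het 1, SAHH-het 3 or any SAHH-het+betaine library was left out, and 5 with sample weights. The levels of both genes set the libraries labelled SAHH-het apart from all others, against the ApoE-null label, and no value here separates betaine from genotype as the source of the return. Both comparisons use the SAHH-het libraries, which makes opposite signs common by chance. Across genes, which are not independent replicates, the fold changes correlated at -0.59, against a simulated median of -0.59 for unchanged groups (100 draws, -0.90 to 0.04). The share of genes with opposite signs was 68.6%, against 69.4% simulated. The covariance was -0.197 against -0.106 simulated, a difference of -0.0906, and 24 of 100 draws were as negative. These draws treat all libraries as unpaired. With same-numbered SAHH-WT and SAHH-het libraries correlated at their mean of 0.233, the simulated medians were -0.49 for the correlation and -0.0963 for the covariance, and 41 and 15 of 100 draws were as negative. None of these 3 values across genes stands out from the draws, which share the SAHH-het libraries as the comparisons do.

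**Figure D3:**
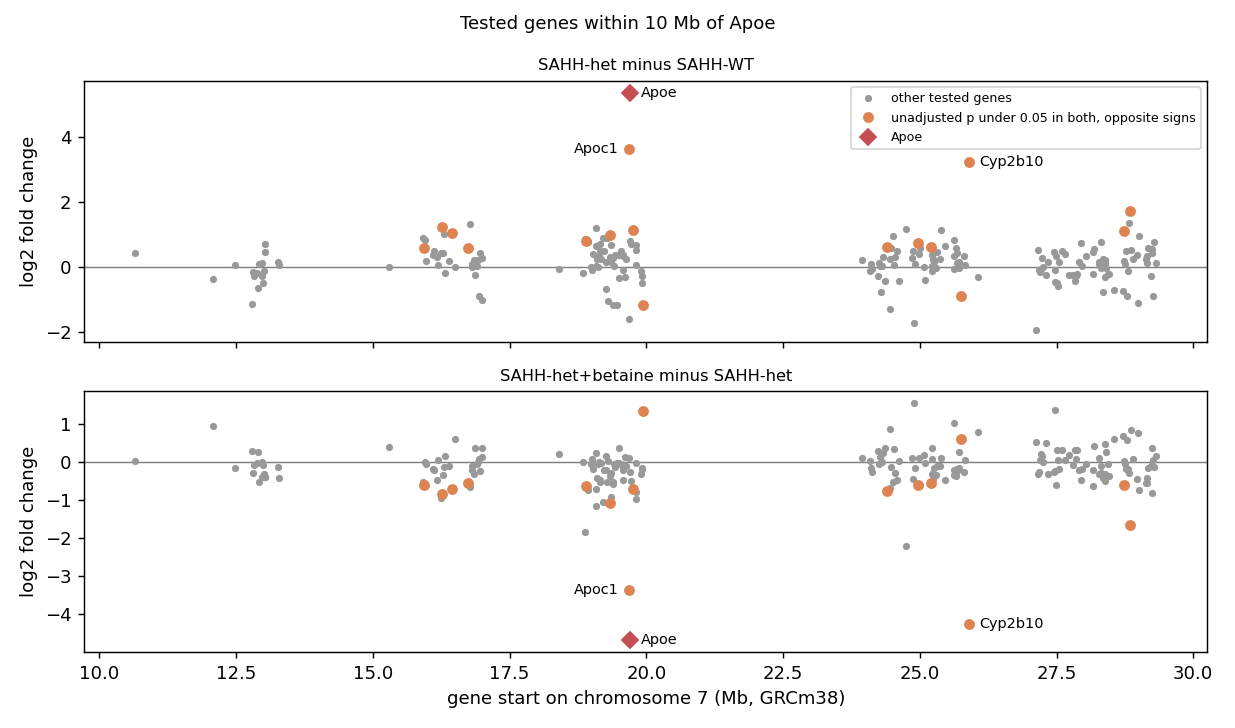
Log2 fold change of tested genes within 10 Mb of Apoe on chromosome 7 (x axis, gene start in Mb, GRCm38) for SAHH-het minus SAHH-WT (top) and SAHH-het+betaine minus SAHH-het (bottom). The diamond is Apoe, the orange points are genes with an unadjusted p under 0.05 in both comparisons and opposite signs, and Apoe (5.36 and -4.69) and Apoc1 (3.63 and -3.37) were called in both.

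The comparison of SAHH-het+betaine with SAHH-WT asks what still differs after betaine. No single gene passed. By camera with its preset correlation, lists of mitochondria, fat and lipid synthesis were higher in SAHH-het+betaine, and lists of neutrophils, senescence, protein folding, macrophages and the cell cycle were lower. All of these list calls were lost with an estimated correlation (adjusted p from 0.745 to 0.828 with an estimated correlation), and those for macrophages, the cell cycle, mitochondrial dynamics and cholesterol synthesis were also lost without each of 4 single libraries in turn, and that for heat shock without each of 3. limma called 0 of 15610 genes, with 1251 at an unadjusted p under 0.05 (794 higher, 457 lower) against 780.5 expected by chance, and limma with voom on recovered fragments called 0 as well. In 16.9% of tested genes the groups did not overlap, against 10% by chance. The smallest adjusted p was 0.618, shared by the genes named next.

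Of the genes with the smallest p, higher values were seen for Dagla, which makes the endocannabinoid 2-arachidonoylglycerol (log2 change 1.72), the mitochondrial ATP synthase gene mt-Atp8 (2.35), the kinase gene Dyrk1b (0.99) and D5Ertd579e (0.95). The microRNA gene Mir6236 measured 1.44 to 3.75 FPKM in SAHH-het+betaine, 0.453 FPKM in SAHH-WT 2, and was listed at 0 in SAHH-WT 1 and 3. Lower values were seen for Cyp1b1 (-1.47), the membrane receptor gene Mmd2 (-0.86) and the DNA repair gene Rbbp8 (-0.81). The microRNA gene Mir8094 and the T cell receptor segment Trbj2-3 were listed at 0 in all SAHH-het+betaine libraries and measured 2.86 to 3.23 FPKM and 1.00 to 6.44 FPKM in SAHH-WT. Mir6236, Mir8094 and Trbj2-3 are very short genes, so these FPKM values rest on few fragments.

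Camera with its preset correlation called 13 of the 42 lists, 7 higher and 6 lower. None passed with fry, whose lowest adjusted p was 0.127, or with an estimated correlation, where the unfolded protein response had an adjusted p = 0.745 with an estimated correlation and the other 12 an adjusted p = 0.828 with an estimated correlation. Over the lists 0 members passed over all genes tested. Adjusted over the list alone, 4 passed, Cpt1b and the fibroblast gene Clec3b as higher and Cdkn2a and the mesothelial transcription factor Wt1 as lower.

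Mitochondrial and lipid genes were higher as lists. All 20 oxidative phosphorylation genes were higher (median 0.93, camera adjusted p = 2.67e-06), with log2 changes of 1.31 for Ndufb8 and 0.99 for Cox5b. All 11 fatty acid synthesis genes were higher (median 1.28, camera adjusted p = 2.50e-05), with 1.63 for the carboxylase gene Acacb and 0.99 for its carbohydrate-responsive regulator Mlxipl. In fatty acid oxidation 11 of 12 were higher (median 1.24, camera adjusted p = 0.000186), with 1.98 for the receptor gene Ppara and 1.45 for Hadha. White adipocyte genes (12 of 14 higher, median 1.04) and brown adipocyte genes (11 of 12, median 1.30) each had a camera adjusted p = 0.000235, with 1.43 for Plin1 and 1.26 for Plin4 and with 1.17 for Cpt1b and 0.65 for the brown fat regulator Prdm16. Cholesterol synthesis (10 of 13 higher, median 0.63, camera adjusted p = 0.0371) had Insig1 at 1.52 and Hmgcs1 at 0.74. Mitochondrial dynamics and mitophagy (11 of 12 higher, median 0.15, camera adjusted p = 0.0438) had the fusion genes Opa1 at 0.96 and Mfn2 at 0.91, and was not called after the correction for exon length (adjusted p = 0.0725). With TPM rescaling, which shifted the median of all genes by -0.33, the median of this last list was -0.18. Without SAHH-WT 1, the library with adrenal genes, the medians were 0.44 for oxidative phosphorylation, 0.52 for fatty acid oxidation, 0.36 for white and 0.42 for brown adipocytes.

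Neutrophil genes were lower in 11 of 11 (median -2.23, camera adjusted p = 2.67e-06), with S100a9 at 93.1 FPKM in SAHH-WT and 5.89 FPKM in SAHH-het+betaine and Retnlg at 13.7 and 1.31 FPKM. SAHH-WT 3 was at the level of the SAHH-het+betaine libraries, with a mean log2 value over the list of 0.59 against -0.14 to 0.67 there, while SAHH-WT 1 and 2 had 3.27 and 3.17. In the senescence list 11 of 12 were lower (median -0.42, camera adjusted p = 0.00153), with log2 changes of -1.60 for Cdkn2a and -1.06 for Gdf15. In the unfolded protein response 12 of 15 were lower (median -0.23, camera adjusted p = 0.0127), with -1.18 for Sdf2l1 and -0.70 for the chaperone Hsp90b1. Macrophage genes were lower in 15 of 16 (median -0.34, camera adjusted p = 0.0349), with -0.88 for the chemokine receptor gene Cx3cr1 and -0.87 for Cd68. Cell cycle genes were lower in 16 of 16 (median -0.32, camera adjusted p = 0.0414), with -0.71 for Mcm3 and -0.60 for Mcm2. Heat shock genes were lower in 8 of 9 (median -0.18, camera adjusted p = 0.0438), with -0.95 for Hspa1b and -0.63 for Hspa8. The calls for macrophages, cell cycle and mitochondrial dynamics were each lost without SAHH-WT 2, SAHH-WT 3, SAHH-het+betaine 2 or SAHH-het+betaine 3 (adjusted p from 0.0526 to 0.629). That for cholesterol synthesis was lost without SAHH-WT 2, SAHH-WT 3, SAHH-het+betaine 1 or SAHH-het+betaine 3 (adjusted p from 0.0935 to 0.190), and that for heat shock without SAHH-WT 3, SAHH-het 2 or SAHH-het+betaine 1 (adjusted p from 0.0607 to 0.349).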

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

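The alternatives chosen after seeing the data were limma with voom on recovered fragments, a block in SAHH-WT and SAHH-het only, and a correction for exon length with and without that block. Over all alternatives, 4170 values for named genes and lists kept direction and side of the threshold, 99 kept direction but no longer passed, 12 newly passed and 26, all of genes, changed sign, and the cause was not tested unless stated. Lists were counted by the direction of camera. By its median 1 list also changed sign, mitochondrial dynamics and mitophagy in SAHH-het+betaine minus SAHH-WT, with -0.18 with TPM rescaling. Genes called in SAHH-het minus SAHH-WT numbered 4 in the main test, 7 with no filter (4 higher and 3 lower), 2 with TPM rescaling and 1 with only the 2 groups compared, where fewer libraries entered. Genes called in SAHH-het+betaine minus SAHH-WT numbered 3 with no filter and 3 with sample weights, and with sample weights 6 genes were called in SAHH-het+betaine minus SAHH-het and 5 were moved back. At an unadjusted p under 0.05 the 3 comparisons gave 1945, 1254 and 1251 genes. Lists called in SAHH-het minus SAHH-WT numbered 20 with no filter and 25 with sample weights, and 22 lists were called with sample weights in SAHH-het+betaine minus SAHH-WT. With an estimated correlation and with fry, 0 lists were called in each of the 3 comparisons. TPM rescaling shifted the median log2 change of all genes by -0.27 in SAHH-het minus SAHH-WT and by -0.33 in SAHH-het+betaine minus SAHH-WT. With it, 9 lists were called higher and 9 lower in SAHH-het minus SAHH-WT, against 4 and 9, and quantile normalization gave 3 higher and 15 lower. In SAHH-het+betaine minus SAHH-WT, TPM rescaling gave 9 higher and 5 lower, against 7 and 6.

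Leaving out single libraries, the genes called ranged over 1 to 5 in SAHH-het minus SAHH-WT (1 without SAHH-WT 2 or SAHH-het 3, 2 without SAHH-WT 3, SAHH-het 1 or any SAHH-het+betaine library), 1 to 4 in SAHH-het+betaine minus SAHH-het (1 without SAHH-WT 3, SAHH-het 1, SAHH-het 3 or any SAHH-het+betaine library), and 0 to 2 in SAHH-het+betaine minus SAHH-WT (2 without SAHH-WT 1, 1 without SAHH-het 2). Genes moved back ranged over 1 to 3. Lists called ranged over 12 to 26 (22 without SAHH-WT 1, 26 without SAHH-het 2), 9 to 15 (15 without SAHH-het 2) and 9 to 25 (25 without SAHH-WT 1).

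Most values that changed sign belong to genes with small changes, but Ucp1 (2.12 in the main test) and Jchain (0.72) also did. In SAHH-het minus SAHH-WT, Col4a1 had a log2 change of -0.24 with TPM rescaling, -0.16 with quantile normalization, -0.30 with sample weights and -0.00207 with voom. In SAHH-het+betaine minus SAHH-het, Col4a2 had 0.00590 with quantile normalization, 0.26 with sample weights and 0.0122 with voom. Ahcy had 0.20 with sample weights in SAHH-het+betaine minus SAHH-WT, and ranged from -0.15 (without SAHH-WT 2) to 0.18 (without SAHH-WT 1) leaving out single libraries. Leaving out single libraries in SAHH-het minus SAHH-WT, Col4a1 ranged from -0.57 (without SAHH-het 2) to 0.49 (without SAHH-het 1), Ucp1 -0.25 (without SAHH-WT 1) to 3.82 (without SAHH-WT 3), Ahcyl1 -0.0212 (without SAHH-WT 1) to 0.87 (without SAHH-het 2), Cfd -0.63 (without SAHH-het 2) to 0.72 (without SAHH-het 1), Alkbh5 -0.14 (without SAHH-het 3) to 0.10 (without SAHH-het 1) and Col4a2 -0.18 (without SAHH-het 2) to 0.63 (without SAHH-het 1). In SAHH-het+betaine minus SAHH-het, Col4a1 ranged from -0.23 (without SAHH-het 1) to 0.82 (without SAHH-het 2), Col4a2 -0.34 (without SAHH-het 1) to 0.46 (without SAHH-het 2) and Jchain -0.11 (without SAHH-het+betaine 1) to 1.13 (without SAHH-het+betaine 3).

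With the replicate number as a block in all 3 groups, limma called 1, 1 and 0 genes, 1 gene was moved back, and 17, 11 and 10 lists were called. Apoe was the gene called in each of the first 2 comparisons, and in SAHH-het minus SAHH-WT Apoc1 (adjusted p = 0.123), Map3k6 (0.129) and Gstt2 (0.149) were not. With the block in SAHH-WT and SAHH-het only, limma called 5 genes in SAHH-het minus SAHH-WT, Apoe, Apoc1, Map3k6, mt-Tg and mt-Atp8, and 17 lists. These were the 13 called without it and those of neutrophils, fatty acid oxidation, the circadian clock and the unfolded protein response, with no list passing with an estimated correlation. The correction for exon length gave 4, 2 and 0 genes and 16, 10 and 12 lists, with 2 genes moved back, and Alkbh5 had 0.00273 in SAHH-het minus SAHH-WT. Together with the block in SAHH-WT and SAHH-het it gave 5 genes and 16 lists in that comparison, again with 0.00273 for Alkbh5. A fold change of 2 was recovered for 10% of simulated genes in SAHH-het minus SAHH-WT, so changes of that size in single genes were mostly not detectable with 3 libraries per group.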

Other observations

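The adrenal, hepatocyte and thymocyte lists, the tests of macrophages as a source of Apoe and of liver RNA and heterozygosity for Ahcy, the wider gene set and random windows around Apoe and the comparison with exon length were chosen after the results were seen. On the mitochondrial chromosome, none of mt-Co3, mt-Nd3, mt-Tr and mt-Nd4l around mt-Tg passed (limma adjusted p from 0.351 for SAHH-het minus SAHH-WT and from 0.494 for SAHH-het+betaine minus SAHH-het). The log2 changes in these 2 comparisons were 1.72 and -1.47 for mt-Nd3 and 2.64 and -3.51 for mt-Tr, which follow mt-Tg, 1.22 and -0.71 for mt-Co3, which precedes it, and -0.02 and 0.76 for mt-Nd4l, which lies beyond mt-Tr. mt-Nd3 (9459 to 9806), a subunit of respiratory complex I, measured 762, 326 and 360 FPKM in SAHH-het, 79.5, 102 and 309 FPKM in SAHH-WT and 98.1, 167 and 254 FPKM in SAHH-het+betaine. The tRNA gene mt-Tr (9808 to 9875) measured 70.2, 23.0 and 11.8 FPKM in SAHH-het, 0.820 to 8.65 FPKM in SAHH-WT and 1.12 to 2.61 FPKM in SAHH-het+betaine. The ATP synthase gene mt-Atp8, at 7766 to 7969, measured 0.962 to 3.40 FPKM in SAHH-WT and 8.16 to 19.2 FPKM in the other groups. It did not pass (limma adjusted p = 0.246 for SAHH-het minus SAHH-WT and 0.618 for SAHH-het+betaine minus SAHH-WT), except in the former with the block in SAHH-WT and SAHH-het (adjusted p = 0.0461). Per1 and Per2, repressors of the circadian clock, passed adjusted over the list alone as lower in SAHH-het+betaine than in SAHH-het, with log2 changes of -1.44 and -1.96, while the clock list did not pass (5 of 13 higher, camera adjusted p = 0.172).

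Neither muscle list passed in SAHH-het minus SAHH-WT. For cardiac muscle 9 of 11 genes had lower values (median -2.78, camera adjusted p = 0.0525, adjusted p = 0.743 with an estimated correlation), through SAHH-WT 2 and 3, with mean log2 values of 4.19 and 2.84 over the list, while SAHH-WT 1 was at 0.50, within the SAHH-het range of 0.31 to 1.27. For skeletal muscle 12 of 12 had higher values (median 2.04, camera adjusted p = 0.225), but the libraries were at 8.20, 4.41 and -0.05 in SAHH-het and 6.64, 0.34 and 0.10 in SAHH-WT, so the direction rests on single libraries. In SAHH-WT 1, 10 of 10 adrenal cortex genes and 8 of 9 adrenal medulla genes had their highest value of all libraries, with Star at 1128 FPKM and Chga at 769 FPKM, against 1 of 10 hepatocyte and 0 of 7 thymocyte genes. Th and Dbh, which nerves of the sympathetic system also express, reached 79.3 and 72.6 FPKM in SAHH-het 1. All 9 libraries had Xist at 22.9 to 50.8 FPKM, and Ddx3y, Uty, Kdm5d and Eif2s3y were listed at 0 in all of them. Across 12992 protein-coding genes, which are not independent replicates, the log2 change had a Spearman correlation with exon length of -0.20 for SAHH-het minus SAHH-WT, 0.18 for SAHH-het+betaine minus SAHH-het and -0.06 for SAHH-het+betaine minus SAHH-WT. In the first of these the median change was 0.28 for the shortest 10% and -0.13 for the longest 10%. Within libraries the correlation ran from -0.27 (SAHH-het 1) to 0.24 (SAHH-het+betaine 1), so it differed within groups too. The median exon length was 984 for neutrophil genes and 8098 for collagens and elastic fibres, against 4343 over all genes. After the correction for exon length the correlations were -0.03, 0.03 and 0.00785, and all lists called in the first 2 comparisons stayed called, as did 12 of 13 in the third.

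Apoe was higher in the libraries labelled SAHH-het than in all 6 others. The tables argue against liver RNA, since the hepatocyte list had a median log2 change of -0.0546 and Alb did not exceed 1.29 FPKM, and against more macrophages, since the upper quartile of the macrophage list was 0.0850 where Apoe had 5.36. A candidate explanation, as a hypothesis, is that these libraries lack the chromosome segment of the Apoe-null allele. Of the 4 other genes called, 1 lies within 10 Mb of Apoe, against 1.42% of tested genes (one-sided Fisher exact p = 0.0555). Among 507 genes that differed from both groups at unadjusted p without Apoe and Apoc1, 15 lie there (one-sided Fisher exact p = 0.00561). A share of the window's genes as high was reached in 26 of 947 random windows. The Fisher tests treat neighbouring genes as independent, and the trend of the changes with exon length was not taken out of them. The hypothesis stays open, because 4 called genes are few. Every SAHH-het library shares the SAHH genotype and the Apoe level, which cannot be told apart here, and an effect of the SAHH genotype on Apoe was not tested.

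Ahcy was at the SAHH-WT level in the libraries labelled SAHH-het+betaine. The tables argue against the scaling of the libraries, since the lowest log2 change of Ahcy from SAHH-het was 0.93 over the scaling alternatives. They also argue against liver RNA, since the upper quartile of the rise over the hepatocyte genes was 0.109 FPKM, where Ahcy rose by 4.62 FPKM. If these animals were not heterozygous, the change from SAHH-WT would be near 0. It was -0.0153, which restates the level that raised the question. That betaine may raise Ahcy predicts a rise from SAHH-het but fixes no size, so this value does not test it. The 2 explanations cannot be told apart, because all 3 libraries of the group share genotype label and treatment. A difference in tissue content other than liver was not tested as a source. The change of Ahcy from SAHH-het did not pass over all genes (limma adjusted p = 0.460). Apoe in these libraries, at 5.51 to 8.88 FPKM, was also near SAHH-WT (2.91 to 6.11 FPKM) and far from SAHH-het (149 to 225 FPKM).

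The lists of MHC class II, T and NK cells and B and plasma cells were lower in SAHH-het than in SAHH-WT. Unequal amounts of lymphoid tissue in the libraries may contribute. With the level of the B and plasma cell list as a covariate, the median log2 change of MHC class II moved from -1.86 to -1.02 and that of T and NK cells from -1.69 to -0.49, while lists of other cells moved too or stayed, adventitial fibroblasts from -0.72 to -0.76, collagens from -0.75 to -0.54, oxidative phosphorylation from 0.91 to 1.24 and brown adipocytes from 1.84 to 2.40. A change in lymphoid cells with SAHH genotype and an unequal share of lymphoid tissue cannot be told apart, because all 3 SAHH-het libraries had low levels and no value gives the tissue taken. With this covariate limma called 1 gene (Apoe), 2 genes (Apoe and mt-Tg) and 0 genes in the 3 comparisons.

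The 6 libraries of each comparison can be split in 10 ways, which is too few for a share under 0.05. The real split gave 4 genes for SAHH-het minus SAHH-WT, where 1 of 10 splits gave as many and the highest other gave 1. The 3 other splits that also part all same-numbered libraries of these groups gave 0 each, and the remaining splits part 1 pair. It gave 3 for SAHH-het+betaine minus SAHH-het, where 1 of 10 splits gave as many and the highest other gave 0. For SAHH-het+betaine minus SAHH-WT the real split gave 0, so all 10 of 10 splits gave as many, and the highest other gave 86. That split set SAHH-WT 2, SAHH-WT 3 and SAHH-het+betaine 1 against the others, with 85 of its 86 genes higher in the former, among them 9 of 13 T and NK cell genes, 4 of 12 B and plasma cell genes and 3 of 7 MHC class II genes. It points to a structure of the samples by lymphoid genes that the groups do not follow.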
